A study of Mus musculus with 16 samples.

How the data were processed

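Gene expression was measured on 16 Clariom S arrays, 4 in each of 4 groups, from cells of the mouse olfactory mucosa sorted by fluorescence. The groups were GFP+ and GFP- cells of mice given an odorant and GFP+ and GFP- cells of mice given vehicle. Each array held biotin-labelled cRNA from 50 to 100 ng of total RNA of cells pooled from 3 mice. With 24 mice in the study and 3 per pool, the GFP+ and GFP- arrays of 1 treatment and number came from the same pool, which makes 8 pools. The sample labels name the odorant as bourgeonal and the series title names indole, so its identity stays open and it is called the odorant here.

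The deposited values are log2 probeset signals, which the authors made with Affymetrix Expression Console. Its version and the methods of background correction, normalization and summarization are not given in the sources used here. The values were used as deposited, with no further scaling. Of 28846 probesets in the deposited table, 6640 control probesets were left out, which left 22206 gene probesets. Of these, 19572 carried 1 gene symbol, 0 carried several and 2634 carried none. All 19572 were matched by gene ID to a RefSeq gene table, which changed 0 symbols. Of the symbols, 55 stood on more than 1 probeset (122 probesets), and each probeset was tested on its own. The genome build of the array annotation is not given in the sources used here, so no positions are printed. No column of the table was without a sample (0 of 16).

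Signal over background was judged on each array against the 95th percentile of 23 antigenomic control probesets, which match no mouse sequence. A group was called at background for a gene when none of its arrays exceeded that level. A fold against such a group, or against a group whose mean did not exceed the mean level of its arrays, is given as a lower bound. It was computed with the background level in place of any value under it, and no fold is given when both groups were at background. The number of arrays limits the precision, and errors are standard errors (SE) of the fit or standard deviations (SD) over 4 arrays.

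There were 5 comparisons: odorant against vehicle in GFP+ cells, the same in GFP- cells, GFP+ against GFP- cells with vehicle, the same with odorant, and the interaction, which is the odorant effect in GFP+ cells minus that in GFP- cells. Each of the first 4 used the 8 arrays of its groups and the interaction used all 16. Each was fitted with limma (lmFit and eBayes, version 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all 22206 gene probesets and a threshold of 0.05. The 1080 odorant receptor probesets were also adjusted over the list alone. Another 29 lists covered other chemosensory receptors, neuronal genes, markers of the other cell types of the mucosa, and stress, clock and housekeeping genes. All 30 were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 30 lists of a comparison. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

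The comparisons, lists, alternatives and named genes were chosen before the data were examined, except where the closing section says otherwise. Named genes were, per comparison, the 10 largest rises and 10 largest falls past the threshold (predicted genes with Gm or Rik symbols passed over). To these were added the 15 higher and 5 lower odorant receptors with the smallest p past the threshold over the list alone. Where no receptor passed, the 5 with the smallest p were taken. S100a5, Omp and Kirrel2 were always included, together with 2 to 4 members with the smallest p of each list described. Olfr578, Eif2s3y, Uty, Kdm5d, Olfr323, Fam183b, Bpifb9b, Bpifa1, Ifit3, Ifit3b and the clock genes in the closing section fall outside this rule and were named after their values were seen.

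The fits were tested on simulated data in which 200 of the 22206 genes, 100 of them odorant receptors, were shifted by a known amount. Errors were drawn independently for each gene and array, whereas genes of real arrays vary together. Receptors at background received the full shift. The rates below may therefore be higher than in the real data. In the GFP+ comparison of odorant with vehicle, 30% of genes shifted by 1 log2 unit were called, 84% of those shifted by 2 and 92% of those shifted by 3, with 5 false calls among 108. Of receptors adjusted over the list alone, 52%, 96% and 100% were called at those sizes. In the interaction, 20%, 70% and 94% of genes were called, with 8 false calls among 101 (7.92%). False calls were 2 of 112 in GFP- cells. Between the fractions they were 7 of 127 (5.51%) with vehicle and 3 of 108 with odorant.

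The numbers of the replicates were checked for pairing through correlations, across genes, of values centred within each group. Between GFP+ and GFP- arrays of the same number, r was 0.11 to 0.16 with vehicle, where 8 of 8 arrays matched best with their own number, and 0.014 to 0.36 with odorant, where 5 of 8 did. A fit with the replicate number as a block was therefore run as an alternative. With that block, 1682 genes were higher and 2237 lower in GFP+ cells with vehicle, and 883 were higher and 1817 lower with odorant. The other alternatives were quantile normalization anew, subtraction of array medians, leaving out dim probesets (below the 40th percentile), an adjusted p of 0.1, a minimum log2 difference of 1, an estimated correlation for the list tests, and leaving out each replicate in turn. The planned test of receptor subfamilies was not run, since no receptor was called higher with the odorant and the reference table held no subfamily names.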

Results

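Olfactory sensory neurons, the odor-detecting cells of the nose, each express 1 member of a very large family of odorant receptor genes. In S100a5-tauGFP mice, green fluorescent protein (GFP) reports the S100a5 gene, whose expression in these neurons depends on their activity. Male and female mice aged 7 to 12 weeks, 24 in all, spent 40 h alone in chambers with clean air flowing at 3.1 L/min. From 26 h on, for 14 h, they received pulses of 10 s every 20 min of either an odorant or filtered air (vehicle). The labels name the odorant as bourgeonal and the series title as indole, so which was used stays open. Cells pooled from 3 mice were sorted into GFP+ and GFP- fractions, which gave 4 groups of 4 arrays.

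Array medians over the gene probesets were 6.29 to 6.38 (log2 signal) in GFP+ cells and 6.64 to 6.76 in GFP- cells. Between 46.7% and 50.9% of probesets exceeded the background level of their array (6.57 to 6.87), as did 732 to 841 of the 1080 odorant receptor probesets. Across genes, which are not independent replicates, arrays of 1 group correlated with r of 0.987 to 0.994, and GFP+ with GFP- arrays with r of 0.953 to 0.973. Omp, the marker of mature olfactory sensory neurons, was near the top of the scale in all 4 groups, at 18.69 ± 0.051 (SD, n = 4) in GFP+ cells with odorant and 18.63 ± 0.072 in GFP- cells with vehicle. The Y-linked gene Eif2s3y was at 2.64 to 3.41 in the pools numbered 4 of both treatments and at 9.95 to 11.2 in all others.

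The first comparison asked which odorant receptors and other genes differed in GFP+ cells between mice given the odorant and mice given vehicle. S100a5 was at 15.99 ± 0.31 with odorant and 15.97 ± 0.26 with vehicle, a difference of 0.021 (95% interval -0.40 to 0.44; -0.0985 to 0.166 over fits without single replicates). Kirrel2, an activity-dependent adhesion molecule of olfactory axons, was at 15.16 ± 0.68 and 14.73 ± 0.15, a difference of 0.43 that was 0.168 without odorant replicate 2 and 0.642 without odorant replicate 1. Among odorant receptors, Olfr649 had the smallest p, at 7.40 ± 0.17 with odorant and 8.30 ± 0.34 with vehicle (difference -0.90, SE 0.18). Olfr1204 was at 10.61 ± 0.39 and 9.41 ± 0.78 (difference 1.20, SE 0.35). Olfr878 (difference -1.18, SE 0.24), Olfr385 (0.71, SE 0.19) and Olfr1317 (0.62, SE 0.17) had values at background in both groups. The adjusted p of these 5 receptors, adjusted over the list alone, was 0.30 to 0.64. All 4 odorant arrays lay on the same side of the vehicle mean for each, which the choice by smallest p favours and which is no evidence of an effect.

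In that comparison limma called 0 genes higher and 0 lower, and 848 of 22206 (3.82%) had an unadjusted p under 0.05. It also called 0 odorant receptors, over all genes and adjusted over the list alone, with 69 of 1080 at an unadjusted p under 0.05 (18 higher, 51 lower). The upper 95% bound of the difference lay below 1 log2 unit for 897 receptors and below 2 for 1063, and the median half-width of the interval was 0.634. These counts include receptors at background (732 to 798 of 1080 exceeded it per GFP+ array), for which a narrow interval does not bound a change in expression. Leaving out odorant replicate 3 gave Olfr878 an adjusted p of 0.027 over the list alone (difference -1.42), and leaving out vehicle replicate 4 brought 3 probesets without a gene name past the threshold, with differences of 3.36 to 4.14 and an adjusted p of 0.0053 to 0.0069.

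**Figure D1:**
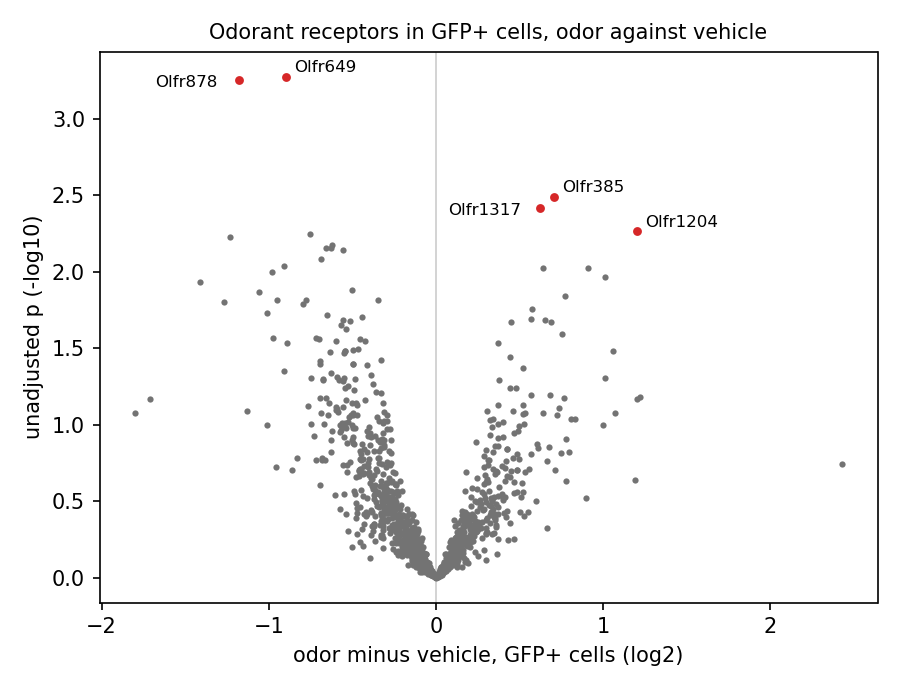
Unadjusted p from limma (-log10, y axis) of each of the 1080 odorant receptor probesets (points) against its difference between odorant and vehicle in GFP+ cells (log2, x axis), from 4 arrays per group, with the 5 of smallest p named and in red. None passed the threshold once adjusted, and 10 receptors lay above 1 and 10 below -1 on the x axis.

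The lists gave few differences in GFP+ cells. None of the 7 activity-dependent genes passed (median difference 0.083), and Lrrc3b was at 14.44 ± 0.52 with odorant and 13.76 ± 0.48 with vehicle. None of the 25 immediate early genes, which neurons switch on within minutes of stimulation, passed either (median -0.058), with Jun at 11.83 ± 0.21 and 12.22 ± 0.28. Adjusted over the list alone, the heat shock gene Hspa1b (difference -0.73, SE 0.16, at background with odorant) and the smooth muscle gene Tagln (-0.56, SE 0.14, at background in both groups) were lower, 1 of 9 members of each of their lists. As a list, odorant receptors had a median difference of -0.079 (mean -0.071, adjusted p = 0.044 with the preset correlation). That call was lost with an adjusted p = 0.69 with an estimated correlation, with adjusted p values of 0.14 after quantile normalization and 0.19 without dim probesets. It was also lost without odorant replicates 1 (0.20) or 4 (0.054) and without vehicle replicates 1 (0.49, mean -0.012) or 4 (0.076).

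In GFP- cells, the same question served as background. Olfr895 was at 5.42 ± 0.23 with odorant and 6.63 ± 0.31 with vehicle, both means under the background level (difference -1.21, SE 0.19, adjusted p = 0.066 over the list alone). Olfr1056 (-0.94), Olfr1302 (-0.93), Olfr619 (-1.13, at background in both groups) and Olfr1202 (0.98) followed, each with an adjusted p of 0.19. Kirrel2 was at 14.10 ± 0.83 and 13.14 ± 0.31 (difference 0.96, SE 0.35, adjusted p = 0.71), S100a5 differed by -0.19 (SE 0.17; -0.311 without odorant replicate 1 and -0.0879 without odorant replicate 2) and Omp by -0.031 (0.0077 with array medians subtracted). Limma called 0 genes and 0 receptors, with 1520 genes (6.84%) and 108 receptors (30 higher, 78 lower) at an unadjusted p under 0.05. Leaving out vehicle replicate 2 brought Olfr895 (-1.35) and Olfr578 (-1.32) to an adjusted p of 0.034 over the list alone.

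Of the lists in GFP- cells, 6 passed with the preset correlation and 0 with an estimated correlation. Ribosomal proteins were lower with odorant (median -0.39, adjusted p = 8.6e-10), with Rpl28 at 15.31 ± 0.50 and 15.83 ± 0.15. Oxidative phosphorylation genes (-0.24, adjusted p = 4.2e-06), odorant receptors (-0.091, 0.027) and the 2 red blood cell genes (-1.1, 0.04) were lower, with Alas2 at 7.51 ± 0.70 and 8.69 ± 0.89 (adjusted p = 0.043 over the list alone). Axon guidance genes were higher (0.19, 0.0018), with Epha7, a receptor for ephrins, at 12.45 ± 0.39 and 11.68 ± 0.14, as were vomeronasal receptors (0.1, 0.0071). For all 6 the adjusted p was 0.87 with an estimated correlation. Immune markers (median -0.36) and globose basal and cell cycle markers (-0.28) each had an adjusted p of 0.086. Immature neuron markers (-0.18) and microvillar and tuft cell markers (0.13) each had 0.17. Among the GFP- arrays with odorant, replicate 1 held the highest mean of immune markers, 9.695 (9.768 in vehicle replicate 3). Without odorant replicate 2 the means of ribosomal proteins (-0.12), oxidative phosphorylation genes (-0.036, adjusted p = 0.42) and axon guidance genes (0.14, adjusted p = 0.15) shrank, and without odorant replicate 1 those of the first 2 grew to -0.62 and -0.39. The receptor call was lost without odorant replicates 1 (adjusted p = 0.19) or 2 (0.42) or vehicle replicates 3 (0.15) or 4 (0.05). The red blood cell call was lost without odorant replicates 1 (0.075), 3 (0.076) or 4 (0.12) or vehicle replicates 2 (0.16) or 3 (0.13), and the vomeronasal call without vehicle replicates 2 (0.11) or 3 (0.14) or dim probesets (0.57).

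The interaction asked whether the odorant effect differed between the fractions. Olfr1317 had a difference of 1.26 between the effects (SE 0.26, adjusted p = 0.19 over the list alone), Olfr159 1.40 (SE 0.33, 0.26), Olfr1056 1.24 (SE 0.32, 0.44), Olfr1417 1.10 (SE 0.29, 0.44) and Olfr878 -1.21 (SE 0.36, 0.74). Olfr1317 and Olfr159 were at background on all 16 arrays, and Olfr878 on the 8 GFP+ arrays. S100a5 had 0.21 (SE 0.26; 0.122 without odorant replicate 4 and 0.335 without vehicle replicate 4), Kirrel2 -0.53 (SE 0.50) and Omp 0.047 (SE 0.15; -0.000705 with array medians subtracted). This fit treated the fractions of a pool as independent. Within pools (the pool as a block), Kirrel2 had an SE of 0.20 (adjusted p = 0.72) and S100a5 of 0.21 (adjusted p = 0.87), and limma again called 0 genes, with 1460 at an unadjusted p under 0.05. Limma called 0 genes and 0 odorant receptors, with 1093 genes (4.92%) and 33 receptors (23 higher, 10 lower) at an unadjusted p under 0.05. Without vehicle replicate 1, Olfr1317, at background throughout, reached an adjusted p of 0.039 over the list alone (difference 1.5). Ribosomal proteins (median 0.4, adjusted p = 0.00011), oxidative phosphorylation genes (0.24, 0.004) and axon guidance genes (-0.24, 0.0015) passed, and were lost at adjusted p values of 0.94, 0.95 and 0.89 with an estimated correlation. All 3 calls were also lost without odorant replicate 4, at adjusted p values of 0.47, 0.64 and 0.067, and without vehicle replicate 3, at 0.22, 0.26 and 0.11. The mean of ribosomal proteins, 0.36, was 0.14 and 0.2 without those replicates and 0.68 without odorant replicate 1, and that of oxidative phosphorylation genes, 0.21, was 0.079 without odorant replicate 4 and 0.43 without odorant replicate 1. Over their lists alone, Taar7a (difference 1.01, adjusted p = 0.04, above background on 8 of 16 arrays) and Vmn1r185 (-1.52, adjusted p = 0.0096, at background on all 16 arrays) passed. Over all genes limma gave them adjusted p values of 0.96 and 0.33.

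The third comparison asked what the sort separated in mice that smelled only filtered air. Odorant receptors split in both directions. Olfr309 was 56.7-fold higher in GFP+ cells (15.88 ± 0.22 against 10.06 ± 1.3, SD, n = 4), Olfr110 47-fold, Olfr536 46-fold and Olfr533 32.4-fold (14.95 ± 0.16 against 9.94 ± 0.29). Olfr393 was at least 209-fold lower (6.13 ± 0.62 against 14.38 ± 0.24) and Olfr1507 at least 178-fold lower. Among the largest falls were also genes typical of neutrophils and other myeloid cells: S100a9, a calcium-binding protein of neutrophils, was at least 309-fold lower in GFP+ cells, and Lcn2, an iron-scavenging protein, 619-fold lower (7.66 ± 0.96 against 16.93 ± 1.1).

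Of the 1080 odorant receptors, 379 were higher and 275 lower in GFP+ cells over all genes, and 426 higher and 313 lower adjusted over the list alone. Quantile normalization gave 456 and 308 over the list alone, and subtraction of array medians 522 and 257. All 10 of the largest rises among named genes were receptors: besides those named, Olfr613 (at least 12.5-fold), Olfr481 (at least 20.5-fold), Olfr372 (at least 24.2-fold), Olfr494 (at least 15.9-fold), Olfr1093 (at least 9-fold) and Olfr1509 (at least 20.9-fold, a gene that also varied between pools in both fractions). Olfr281 (20.6-fold, SE 0.16 log2), Olfr522 (22.6-fold, SE 0.18), Olfr472 (15.5-fold) and Olfr1263 (9.45-fold) were among the higher receptors with the smallest p. Among the lower ones were Olfr794 (at least 71.7-fold), Olfr411 (112-fold), Olfr441 (40.4-fold) and Olfr1297 (303-fold). The adjusted p of all receptors named here was at most 2.4e-05, with 4 of 4 GFP+ arrays on the stated side of the GFP- mean. Of 14 trace amine receptors, a separate family that detects volatile amines, 7 were higher and 6 lower, with Taar9 9.47-fold and Taar4 7.7-fold higher and Taar2 at least 11.2-fold lower (list adjusted p = 0.99).

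S100a5 itself was 1.91-fold higher in GFP+ cells (15.97 ± 0.26 against 15.04 ± 0.15, adjusted p = 0.0024). Of the 7 activity-dependent genes, 6 were higher (median 1.5, adjusted p = 2.1e-06, 0.046 with an estimated correlation): Ptprn, a protein of dense-core vesicles, 4.18-fold, Kirrel2 3.03-fold, Pcp4l1 2.89-fold and Cidea 2.38-fold. That list holds S100a5, by whose reporter the cells were sorted, so it is not independent evidence of its direction. Omp differed by 0.049 (SE 0.12, adjusted p = 0.82; -0.041 after quantile normalization, and 0.41 with an adjusted p of 0.022 with array medians subtracted). That subtraction moved the median of all genes from 0.082 to 0.45, so Omp at 0.41 did not exceed the general shift. Of 22 genes of odor transduction in mature neurons, 5 were higher, among them Pde1c and Slc24a4 (1.57-fold and 1.52-fold), which remove the second messengers cAMP and calcium (list median 0.19, adjusted p = 0.032, 0.28 with an estimated correlation and 0.062 with the replicate number as a block). That call was also lost after quantile normalization (adjusted p = 0.075) and without vehicle replicates 1 (0.056), 3 (0.068) or 4 (0.076). Axon guidance genes had 10 of 21 higher, with the ephrin receptor Epha5 2.1-fold and the semaphorin receptor Plxna3 2.06-fold (adjusted p = 0.0017, 0.071 with an estimated correlation), and presynaptic genes 3 of 17, with Syn1 2.38-fold and Syn2 1.79-fold (adjusted p = 0.0043, 0.062 with an estimated correlation). Some lists share genes: Kirrel2 is also an activity-dependent gene and Epha5 also a low-activity gene, so the axon guidance list is not separate evidence from those lists.

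Immediate early genes were lower in GFP+ cells: 17 of 25 passed (median -1.8, adjusted p = 2e-17, 0.017 with an estimated correlation), with Egr2 58.2-fold, Btg2 33.2-fold, Egr1 29.6-fold and Nr4a3 at least 2.61-fold lower. Markers of immune cells, which moved with them, had 12 of 17 lower (median -1.9, adjusted p = 2.1e-11, 0.074 with an estimated correlation). Of 20 markers of immature olfactory neurons, 11 were lower and 2 higher (adjusted p = 8.5e-10, 0.017 with an estimated correlation), with the transcription factor Nhlh1 at least 11.7-fold and the G protein subunit Gng8 at least 19.8-fold lower. Of 15 markers of globose basal cells, the dividing progenitors, and of the cell cycle, 14 were lower (adjusted p = 1.8e-11, 0.046 with an estimated correlation), with Mki67 at least 13.3-fold lower. Microvillar and tuft cell markers had 13 of 14 lower (median -2.5, adjusted p = 3.4e-15, 0.0039 with an estimated correlation), with the ionocyte transcription factor Foxi1 at least 24-fold and the taste-pathway channel Trpm5 at least 2.96-fold lower.

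The remaining lists in vehicle mice included other cell types of the mucosa. Sustentacular markers, of the supporting cells, had 10 of 13 lower (adjusted p = 1.6e-08, 0.16 with an estimated correlation), with Krt18 13-fold and the cytochrome P450 Cyp2g1 2.34-fold lower. Bowman gland markers had 3 of 11 lower (0.0067, adjusted p = 0.071 with an estimated correlation), with Sox9 at least 7.59-fold lower, and both red blood cell genes were lower (0.0067, adjusted p = 0.19 with an estimated correlation). Of 9 markers of atypical olfactory neurons 3 were lower (median -0.34, but 0.019 with array medians subtracted; 0.0027, adjusted p = 0.062 with an estimated correlation), and of 58 ribosomal proteins 43 (median -0.79, -0.42 with array medians subtracted, 2.9e-19, adjusted p = 0.23 with an estimated correlation). Vomeronasal receptors had 11 of 324 higher over all genes but 0 over the list alone, with Vmn1r22 at background in both fractions (list adjusted p = 0.0043, adjusted p = 0.34 with an estimated correlation, and 0.68 without dim probesets). Lists that did not pass (adjusted p of 0.085 to 0.99) were horizontal basal cells with 3 of 9 lower, olfactory ensheathing glia with 2 of 10 (median -0.046, but 0.32 with array medians subtracted) and mesenchymal cells with 1 of 9 (-0.068, but 0.29). Endothelial cells (8 genes), motile cilia (8), the unfolded protein response (15), heat shock (9) and sex-linked genes (3) had 0 members past the threshold over all genes, although over the list alone 1 heat shock gene was higher and 4 were lower. Circadian clock genes had 1 higher and 1 lower of 16, oxidative phosphorylation 1 and 1 of 79, interferon-stimulated genes 2 and 3 of 18, signal termination genes 4 and 2 of 12, and low-activity genes 1 and 0 of 5. The median, mean and test differed in sign for interferon-stimulated genes (0.097, -0.23, lower), sex-linked genes (0.2, 0.12, lower), the unfolded protein response (-0.0053, 0.048, lower), signal termination genes (0.0081, -0.21, higher), trace amine receptors (0.72, -0.12, higher) and odorant receptors (0.27, -0.044, higher).

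**Figure D2:**
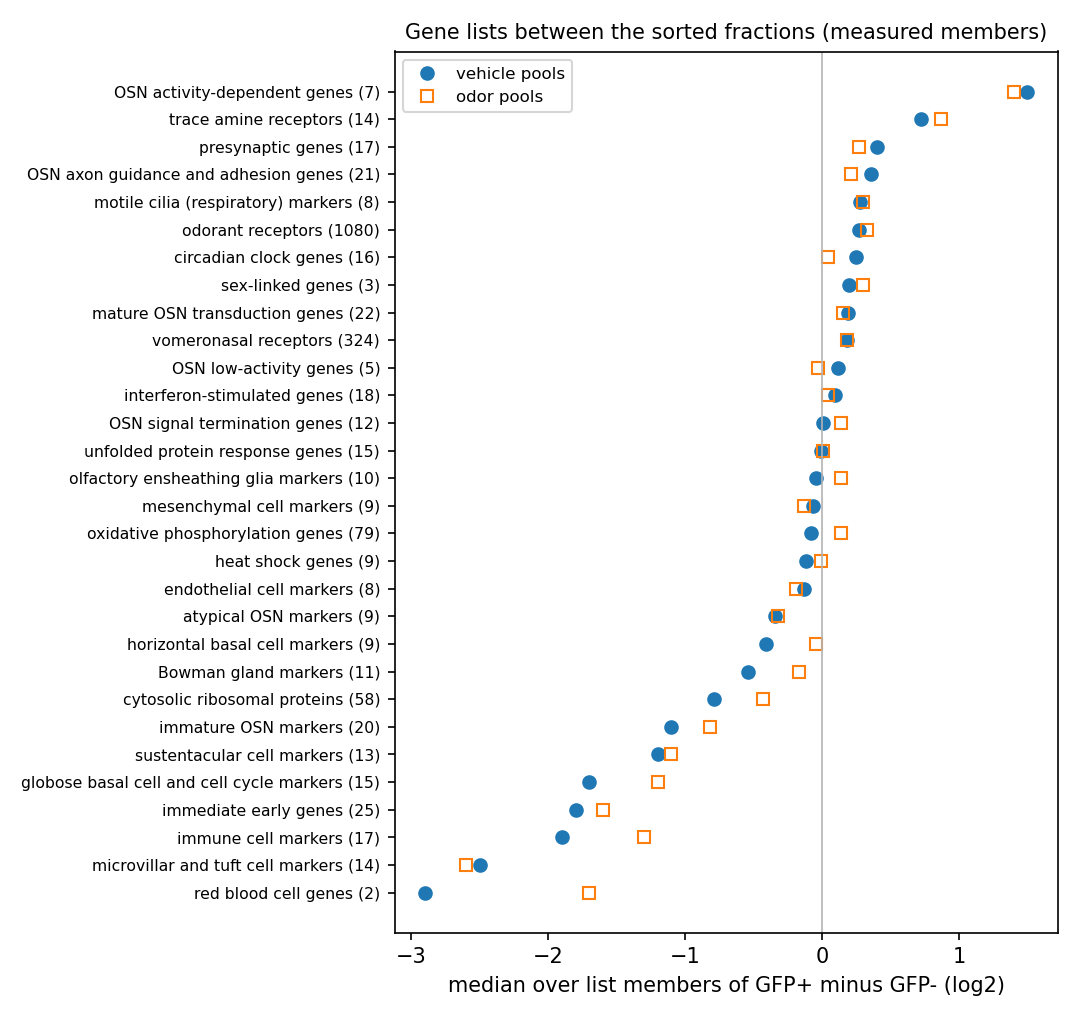
Median difference between GFP+ and GFP- cells (log2, x axis) of each of the 30 lists (y axis), in vehicle and in odorant mice. Microvillar and tuft cell markers (-2.5 with vehicle) lay far to the left of activity-dependent genes (1.5).

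Over all genes, limma called 1723 higher and 2213 lower in GFP+ cells with vehicle (43.8% higher). Quantile normalization gave 2544 and 2034 (55.6%). Subtraction of array medians moved the median difference of all genes from 0.082 to 0.45 and gave 10363 and 1687 (86%), so the balance of directions depended on the scaling. Of the 3936 calls, 3499 and 3409 were kept in the same direction under the scalings, and 0 were reversed. Against that shift of all genes, the medians after subtraction were -1.5 for immediate early genes, 1.9 for activity-dependent genes and 0.55 for mature transduction genes. The higher count was 866, 846 and 1063 without vehicle replicates 1, 2 and 4.

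The fourth comparison asked the same of mice given the odorant. Olfr309 was again among the largest rises, 70.7-fold higher in GFP+ cells (15.53 ± 0.58 against 9.39 ± 0.87, SD, n = 4), with Olfr536 at 56.1-fold, Olfr110 at 48.2-fold and Olfr533 at 41.3-fold. Olfr411 was 137-fold lower (6.83 ± 0.19 against 13.94 ± 0.28), Olfr1297 239-fold, Olfr460 at least 113-fold and Olfr99 at least 132-fold. The neutrophil granule gene Ngp was at least 951-fold lower (6.50 ± 0.46 against 16.74 ± 0.70), Lcn2 at least 791-fold, Retnlg at least 264-fold, S100a9 at least 155-fold and Chil3, a chitinase-like protein of myeloid cells, at least 234-fold.

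Of the 1080 odorant receptors, 368 were higher and 264 lower over all genes, and 430 and 322 adjusted over the list alone (449 and 312 after quantile normalization, 527 and 267 with array medians subtracted). Other large rises were Olfr613 (at least 11.9-fold), Olfr481 (at least 14.5-fold), Olfr494 (at least 15.9-fold), Olfr372 (at least 23.6-fold), Olfr1093 (at least 9.35-fold) and Olfr101 (at least 23.8-fold). Olfr522 (21.5-fold), Olfr593 (10.6-fold), Olfr60 (11.6-fold) and Olfr1111 (18.2-fold) were among the higher receptors with the smallest p, and Olfr77 (at least 46.3-fold), Olfr1384 (at least 40.3-fold) and Olfr1213 (at least 102-fold) among the lower. The adjusted p of all these was at most 2.3e-05, with 4 of 4 GFP+ arrays on the stated side. Of the trace amine receptors, 6 were higher and 5 lower, with Taar4 11.3-fold higher and Taar2 at least 13.7-fold lower.

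**Figure D3:**
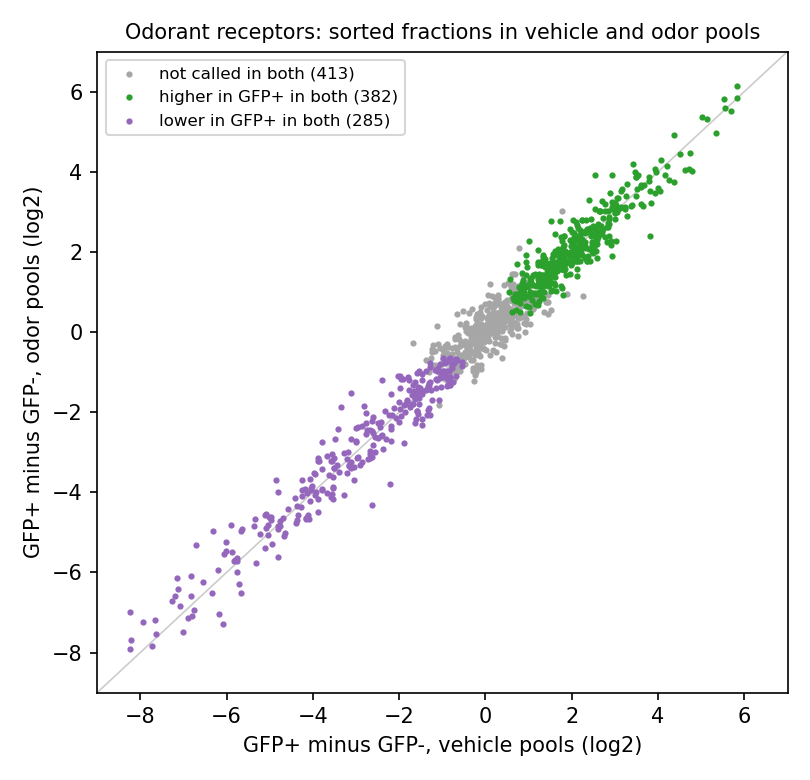
Difference between GFP+ and GFP- cells (log2) of each of the 1080 odorant receptor probesets with odorant (y axis) against that with vehicle (x axis), each from 4 arrays per group. Colors mark the 382 receptors higher and the 285 lower in GFP+ cells in both, and the other 413 are gray. The points follow the diagonal in both directions (r of 0.984 across receptors).

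S100a5 was 2.21-fold higher in GFP+ cells with odorant (15.99 ± 0.31 against 14.85 ± 0.28, adjusted p = 0.0025). Of the 7 activity-dependent genes 5 were higher, with Ptprn 4.08-fold and Pcp4l1 3.33-fold (median 1.4, adjusted p = 1.4e-05, 0.085 with an estimated correlation). Kirrel2 was at 15.16 ± 0.68 against 14.10 ± 0.83 and did not pass (adjusted p = 0.16), but passed with the replicate number as a block (0.0029) and with array medians subtracted (0.028). Omp differed by 0.096 (adjusted p = 0.71), and by 0.41 with an adjusted p of 0.037 with array medians subtracted. That subtraction moved the median of all genes from 0.1 to 0.42, so Omp did not exceed the general shift, and the call of Kirrel2 under it includes that shift. Immediate early genes had 16 of 25 lower, with Egr2 74.3-fold, Egr1 43.1-fold and Fosb 29.1-fold (adjusted p = 5.8e-20, 0.08 with an estimated correlation), and immune markers 13 of 17 (4.9e-15, adjusted p = 0.08 with an estimated correlation). Markers of immature neurons had 11 of 20 lower (4.4e-13, 0.0072 with an estimated correlation), with Dpysl3, which acts in growing axons, 13.1-fold and Nhlh1 at least 11.1-fold lower. Globose basal and cell cycle markers had 12 of 15 lower (2.7e-13, 0.03 with an estimated correlation), with Mki67 at least 8.56-fold. Microvillar and tuft cell markers had 13 of 14 lower (1e-18, 0.0072 with an estimated correlation), with Foxi1 at least 26.6-fold and Coch 11.3-fold lower.

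Of the other lists with odorant, sustentacular markers had 4 of 13 lower, with Krt18 14.4-fold (adjusted p = 5.2e-06, 0.33 with an estimated correlation), atypical neuron markers 3 of 9 (0.0028, adjusted p = 0.094 with an estimated correlation) and red blood cell genes 2 of 2 (0.0087, adjusted p = 0.22 with an estimated correlation). Bowman gland markers had 3 of 11 lower, with Sox9 at least 9.81-fold (list median -0.17, but 0.15 with array medians subtracted; 0.04, adjusted p = 0.34 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.067) and without odorant replicates 1 (0.09) or 2 (0.08). Vomeronasal receptors had 4 higher and 1 lower of 324, 0 over the list alone (0.034, adjusted p = 0.22 with an estimated correlation). That call was lost after quantile normalization (0.42), without dim probesets (0.38) and without odorant replicate 4 (0.074). Ribosomal proteins had 1 of 58 lower, 0 over the list alone (median -0.43, -0.12 with array medians subtracted, 2.2e-05, adjusted p = 0.75 with an estimated correlation), and without odorant replicate 1 their mean of -0.43 was -0.11 (adjusted p = 0.22), and without odorant replicate 4 it was -0.65. The array median of the GFP- cells of odorant replicate 1, 6.76, was the highest of its group. Lists that did not pass (adjusted p of 0.11 to 0.98) were mature transduction genes with 2 of 22 higher (median 0.15, adjusted p = 0.11), presynaptic genes with 1 of 17 higher (median 0.27, adjusted p = 0.11) and axon guidance genes with 1 higher and 1 lower of 21 (median 0.21, adjusted p = 0.42). Motile cilia had 1 of 8 higher, mesenchymal cells 1 of 9 lower, the unfolded protein response 1 of 15, clock genes 1 of 16 and oxidative phosphorylation 1 of 79. Interferon-stimulated genes had 1 higher and 2 lower of 18, and signal termination genes 2 and 2 of 12. Horizontal basal cells, ensheathing glia, endothelial cells, heat shock, sex-linked and low-activity genes had 0 members past the threshold. Odorant receptors (adjusted p = 0.54) and trace amine receptors (0.98) did not pass as lists either.

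Over all genes, 793 were higher and 1742 lower with odorant (31.3% higher), 1266 and 1662 (43.2%) after quantile normalization, and 7757 and 1520 (83.6%) with array medians subtracted, which moved the median of all genes from 0.1 to 0.42. Of the 2535 calls, 2360 and 2307 were kept under the scalings and 0 were reversed. The higher count was 522 and 507 without odorant replicates 1 and 4.

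**Figure D4:**
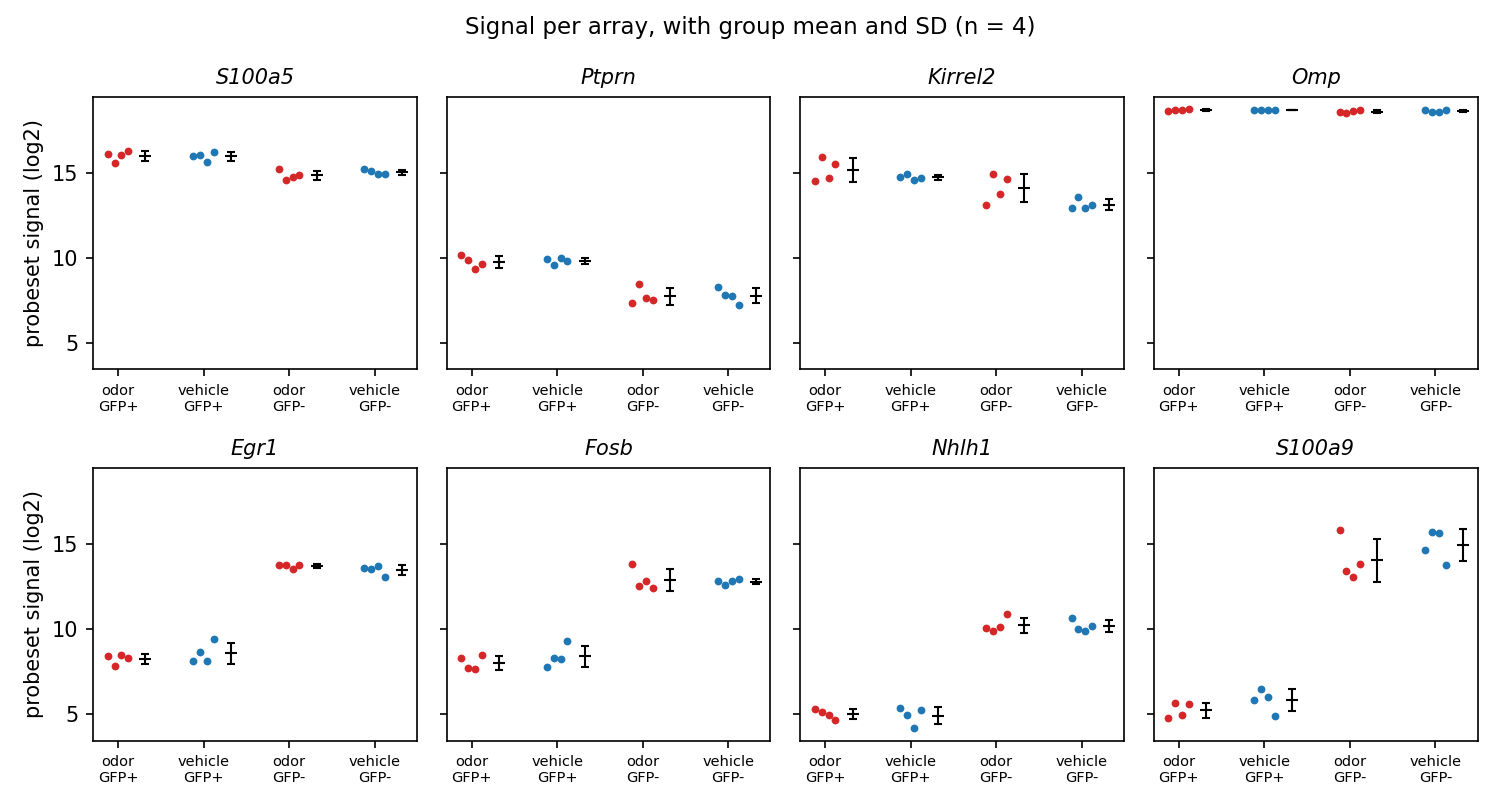
Signal (log2, y axis) of S100a5, Ptprn, Kirrel2, Omp, Egr1, Fosb, Nhlh1 and S100a9 on each array of the 4 groups (x axis), with the mean and SD of 4 arrays. S100a5 lay near 16 in both GFP+ groups, and S100a9 was at 5.82 and 5.24 there against 14.92 and 14.04 in GFP- cells.

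The vehicle and odorant sorts share no arrays. Across odorant receptors, their differences correlated with r of 0.984, and 382 receptors were higher in both (170 expected at random) and 285 lower in both (93.3 expected), with 0 called in opposite directions. Across all genes r was 0.934, but the Spearman rho was 0.611 and 73% of genes had the same sign. Of all genes, 546 were higher in both (61.5 expected) and 1531 lower in both (174 expected). The single gene called in opposite directions was Vmn1r185, at background in all 4 groups (interaction adjusted p = 0.33).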

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

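The counts of other splits for the sort comparisons and the relation of immediate early genes with immune markers were planned, and all other tests in this part were chosen only after the result was seen. The genes entering that relation were those called lower in the vehicle sort, so its members were set by the result. The GFP- arrays of that sort are among those correlated.

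In GFP+ cells, 10 probesets without a gene name were picked because they had the highest differences, odorant minus vehicle, 2.57 to 4.3 log2 units, with adjusted p values of 0.84 to 1 in limma, although without vehicle replicate 4, whose set mean of 9.9 was the highest of its group, 3 of the 10 passed (differences 3.36 to 4.14, adjusted p = 0.0053 to 0.0069). The mean of the 10 was 11.1 ± 0.68 (SD, n = 4) with odorant and 7.92 ± 1.5 with vehicle, a difference that follows from the choice and was not tested on them again, and 9.23 ± 1.9 and 7.93 ± 1.5 in GFP- cells (exact p = 0.29). The 10 moved together, with a mean pairwise r of 0.87 (0.66 to 0.96) over the 16 arrays, consistent with 1 sequence measured by several probesets. A property of each pool shared by its fractions (r = 0.36 over 8 pools, exact p = 0.38, rho = 0.31, exact p = 0.46, r = 0.4 without the 2 farthest pools, adjusted p = 0.38 over 3 relations) and the background of the arrays (r = 0.48 over 16 arrays, permutation p = 0.064, rho = 0.31, p = 0.23, r = 0.17 without the 2 farthest arrays, adjusted p = 0.096) both stay open. What the probesets measure is not given in the sources used here, and an effect of the odorant on them rests on that 1 omission and stays open.

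The 50 named genes with the highest variance between pools shared by both fractions were taken, genes of the Y chromosome left out beforehand (Eif2s3y, Uty and Kdm5d would have entered), with 23 odorant receptors (2.8 expected, adjusted p = 8e-15 over 30 lists) and the gland genes Bpifb9a and Bpifb9b (adjusted p = 0.0035) among them. The p-values of lists among the 50 come from a hypergeometric test, which treats genes as independent draws. Genes that vary together are not independent, and ranking by shared variance favours genes of wide spread. For these 50, the sex of the pools as the main source was argued against, since 88.8% of the shared variance was left without the 2 pools numbered 4, the only ones with low Y-linked signal, and 77.5% without the trend on the Y-linked signal of all pools (median 84.7% for random trends, 5th percentile 69.8%), while with the 3 Y-linked genes kept in the 50 the values were 54.6% and 50.2%. Sequence variants carried by some pools may contribute. Of the 50, 10 had another of the set among their 5 nearest neighbours on the chromosome (random median 4, 95th percentile 8, permutation p = 0.03). The receptors taken alone did not pass (5 of 23, random median 4, permutation p = 0.28). The others with such a neighbour were Bpifb9a, Bpifb9b, Bpifa1, Ifit3 and Ifit3b, related genes that may vary together without sequence variants. The neighbour count cannot tell these apart. The phase of the daily clock may contribute too, since 4 of 16 clock genes, Per1, Per2, Nr1d1 and Ciart, were in the set (0.041 expected, adjusted p = 1e-06). The genes were picked for varying between pools, so neither source is shown to account for them.

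The immediate early genes called lower in GFP+ cells followed the immune markers called lower over the 8 GFP- arrays (17 and 12 genes, r = 0.81, exact p = 0.0094, rho = 0.81, exact p = 0.022, adjusted p = 0.028 over 3 relations). The r was 0.85 within treatments and 0.97 without the 2 farthest arrays. A scaling difference between arrays as the whole cause was argued against, since the median difference in vehicle mice stayed at -1.5 after array medians were subtracted. Immune cells in the GFP- sort may account for part of the pattern, and immature neurons, progenitors and microvillar cells were also enriched in that fraction. Neuronal activity itself, which the sort is built on, stays open and was not tested.

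Other splits of the same 8 arrays (8 pools for the interaction) into 4 and 4 were counted for each comparison (35 splits, the real one included). In the sort with vehicle 1 of 35, the real one with 3936 genes, gave as many (highest other 0), and with odorant 1 of 35 (2535, highest other 2). That share treats the 8 arrays as exchangeable, but the fractions share pools. The 8 splits that part every pool, with a highest other count of 0 in both, are too few for a share under 0.05. The splits alone therefore cannot exclude chance. For odorant against vehicle the real count was 0 in GFP+ cells (highest other 3), in GFP- cells (highest other 86) and in the interaction (highest other 2). Any split gives at least 0, so that all 35 did so decides nothing there. The split with 86 genes set odorant replicates 1 and 2 and vehicle replicates 2 and 3 against the rest, and a count that high points to a structure of the samples, whose source was not tested. The mean of globose basal and cell cycle markers was 7.586, 7.664, 8.172 and 8.06 on those 4 arrays and 7.142, 7.16, 7.282 and 7.242 on the rest, values looked up after the split was seen.

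Of 368 groups of 4 values examined, 26 held a value far from the other 3, where 18.4 would arise at 1 in 20. In GFP- cells with odorant, replicate 1 had S100a8 at 15.8 (nearest other 13.7), Olfr60 at 10.6 (11.2), the immune marker mean at 9.69 (8.65) and the array median at 6.76 (6.65), while replicate 4 had Olfr1029 at 5.7 (6.04). In GFP+ cells with odorant, Ngp was at 7.18 on replicate 1 (6.34), Ly6c1 at 4.78 on replicate 4 (3.5) and the interferon-stimulated mean at 6.08 on replicate 3 (6.18). The mean of sex-linked genes on replicate 4 was 3.07 in GFP- and 3.29 in GFP+ cells with odorant, and 3.35 and 3.74 with vehicle, where the nearest others were 8.85 to 9.13. In GFP- cells with vehicle, replicate 3 had Olfr878 at 11.1 (12), Olfr794 at 12.9 (12.8) and the Bowman gland mean at 6.93 (6.68), and replicate 2 the low-activity mean at 13.3 (13.4). In GFP+ cells with vehicle, replicate 3 had Olfr1099 at 12.3 (13.1), the activity-dependent mean at 12.8 (13.1), the low-activity mean at 13.8 (13.6) and the axon guidance mean at 12.6 (12.4). Replicate 1 had Olfr159 at 4 (3.8) and Olfr533 at 14.7 (15), replicate 2 had Olfr649 at 7.8 (8.42), and replicate 4 had Olfr506 at 12.5 (12.2), Olfr372 at 11.9 (11.1) and the trace amine receptor mean at 8.7 (8.11).

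The odorant effect differed between GFP+ and GFP- cells, by the interaction test with the preset correlation, for axon guidance genes (mean -0.26), ribosomal proteins (0.36) and oxidative phosphorylation genes (0.21). With an estimated correlation none of the 3 passed (adjusted p = 0.89, 0.94 and 0.95).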

How the results depend on the processing

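All tests in this part were planned except the term for sex and the restriction to receptors above background, which were chosen only after the result was seen. The counts of genes and receptors in the odorant comparisons stayed at 0 under every alternative except those given next, and also with the sex term (run in each fraction) and with the restriction. In GFP- cells 1 receptor was lower at an adjusted p of 0.1, and leaving out single replicates gave 0 to 2. In GFP+ cells such fits gave 0 to 3 genes higher and 0 to 1 receptors lower, and in the interaction 0 to 1 receptors higher. The lists past the threshold in GFP+ cells, 1 as reported, were 0 with an estimated correlation, after quantile normalization and without dim probesets, 2 with the replicate number as a block, and 0 to 5 without single replicates. With an estimated correlation 0 lists passed in GFP- cells, 5 in the vehicle sort, 3 in the odorant sort and 0 in the interaction, where leaving out single replicates gave 0 to 6. The higher count in the vehicle sort was 10363 with array medians subtracted, 2692 at an adjusted p of 0.1, 504 at a log2 difference of at least 1, and 846 to 1215 without single replicates. In the odorant sort it was 1266 after quantile normalization, 7757 with array medians subtracted, 1208, 424 and 507 to 587. A stricter threshold lowers a count by construction. Fewer arrays reduce precision but did not lower every count. Receptors lower in the odorant sort, 322 over the list alone, were 338 without odorant replicate 2. Otherwise the cause was not tested. Omp reversed in sign to 0.0077 in GFP- cells and -0.000705 in the interaction with array medians subtracted, and to -0.0409 in the vehicle sort after quantile normalization. Without single replicates S100a5 in GFP+ cells ran from -0.0985 to 0.166 and Omp from -0.00245 to 0.038. Across treatments, arrays of the same number came from different mice. Their r was -0.034 to 0.25 in GFP+ cells, where 4 of 8 arrays matched best with their own number. In GFP- cells it was -0.1 to 0.3, and 5 of 8 did. Both pools numbered 4 had low Y-linked signal. Their r, 0.25 in GFP+ and 0.3 in GFP- cells, lay above every r between different numbers (at most 0.15 and 0.14). Number 1 had 0.0058 and -0.1, and number 3 had -0.034 and 0.054. Pools of the same number may thus share more than the treatment design provides, and how much of that came from Y-linked genes was not tested. Beyond the list count in GFP+ cells, the block changed the calls of Kirrel2 with odorant (adjusted p = 0.0029) and of mature transduction genes with vehicle (0.062). Signal over background limits the receptors, of which 732 to 841 exceeded it per array.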

Other observations

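The test of receptor families was planned, and the test of receptor classes and the choice of genes that varied between pools were made only after the result was seen.

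Among genes that varied between the pools, the clock genes Per1, Per2, Nr1d1 and Ciart had their highest mean in vehicle pool 3, at 10.1 in GFP+ and 9.69 in GFP- cells, and odorant pool 3 followed at 9.01 and 8.82. Vehicle pool 4 was at 8.11 and 7.34. Olfr323 was at 11.6, 4.09, 9.81 and 11.6 in GFP+ cells of odorant pools 1 to 4 and at 4.59, 4.56, 10.2 and 8.06 in those of vehicle pools 1 to 4. Fam183b, on the same chromosome 11, was at 8.62, 5.08, 8.01 and 9.24 and at 4.9, 4.95, 8.01 and 6.52 in the same arrays. Bpifb9b, a gland secretory protein, was at 12.5 in GFP+ and 13.1 in GFP- cells of odorant pool 1 and at 8.19 and 8.29 in those of odorant pool 2.

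A hypothesis was that receptors of 1 MOR family, a grouping by protein sequence, were sorted alike. Receptors with a known family were taken if at least 1 array of either vehicle group exceeded background, and for this test if their family held at least 2 such receptors. Among 861 receptors in 150 families, 31.9% of the variance of the vehicle sort difference lay between families, against 17.3% (median) and 20.5% (95th percentile) in shuffled families. The permutation p of 1e-05 is the smallest that 1e+05 shuffles can give (2e-05 adjusted over 2 tests). This is consistent with related receptors being sorted alike, as a share of the spread, although similar sequences may also share signal between probesets, which was not tested. Class I receptors, the fish-like class, had a median difference of 0.37 (98 receptors, 41 higher and 23 lower) and class II receptors 0.41 (828 receptors, 353 higher and 257 lower). The median over all 1080 receptors, those at background included, was 0.27. The difference of -0.034 (permutation p = 0.92) had a 95% bootstrap interval of -0.39 to 0.44 with receptors resampled. With whole families resampled, since related receptors are not independent, it was -0.43 to 0.54, so a difference between the classes stays open.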
